A study of Caenorhabditis elegans with 18 samples.

How the data were processed

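Small RNA of Caenorhabditis elegans was sequenced after cloning by 3 protocols, per the labels. The 18 samples fall into 14 groups by strain and protocol. Animals were grown at 20 °C for about 60 h, and RNA running between standards of 18 and 26 nt was taken from a gel, per the labels' protocols. In the CIP-PNK protocol a phosphatase and a kinase give every RNA a ligatable 5′ end, so that RNAs with 1 or several 5′ phosphates are cloned. In the Terminator protocol an exonuclease removes RNAs with a 5′ monophosphate, such as microRNAs. In the TAP protocol a pyrophosphatase trims 5′ triphosphates. CIP-PNK was used for 11 groups, Terminator for 2 and TAP for 1.

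The deposited values are estimated counts: each line of a file is 1 genomic match of 1 distinct read sequence, with its reads divided by its number of matches by the authors. This was checked on every line, and the values equalled reads over matches within 0.0001. The files hold no read sequence and no gene annotation. The aligner and the genome build are not given in the sources used here. The largest coordinates differ from the chromosome lengths of WBcel235, the assembly of the gene table at hand, so no gene was named by position. All positions printed are the files' own, counted from 1. The files of samples within a group were identical, byte for byte, in wild type CIP-PNK (2 samples), drh-3 (2 samples) and wild type Terminator (3 samples), and were counted as 1 library. Each group therefore holds 1 library, and no difference between groups has a replicate check. No test across samples was possible and no p-value is given.

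Total depth ran from 1494243 reads in glp-4 to 5359617 in the oocyte library. Reads at the right end of chromosome I, from position 15060001, where the ribosomal RNA repeat lies as background knowledge, were set apart as the end block, together with mitochondrial reads. Values in RPM, reads per 1000000, are relative to the remaining reads, which numbered from 1330926 in ekl-1 to 3924982 in wild type Terminator. Other structural RNAs were not removed. Reads that remained were split into 5 kinds. Point loci and 21-nt ends were picked on the CIP-PNK libraries alone, from reads with at most 5 matches. Point loci were 5′ ends with at least 2000 such reads, a commonest length of 20 to 25 nt, and at least 0.80 of the same-strand reads within 40 nt starting within 2 nt of the end. Of the ends that met this, 92 on chromosome IV with a commonest length of 20 or 21 nt were moved to the 21-nt ends, and the other 88 stand in for microRNAs. The 21-nt ends were 5′ ends on chromosome IV with at least 20 such reads, a commonest length of 21 nt and at most 0.10 of their reads longer than 21 nt. They stand in for 21U-RNAs, the Piwi-bound RNAs of the worm. Reads spanning 45 nt or more of genome were taken to cross introns. Reads of 21 to 23 nt outside these kinds are called the 22-nt class, since 22-nt RNAs starting with guanine (22G-RNAs) are made in the worm by RNA-dependent RNA polymerases. The first base is not in the files. The remaining reads are called other lengths.

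The design made before the data were examined planned counts of antisense 22G-RNA per gene. In its place 22-nt-class reads were summed over stranded windows of 1 kb. A window was called lower or higher where its RPM differed at least 2-fold and reached at least 25 in the higher of the 2 libraries. The thresholds, the comparisons and the rule for naming were fixed before the data were examined. The gene lists, the check of each mutated gene and the position along transcripts were also planned, need gene annotation, and were not analysed here. Log2 ratios use a pseudocount of 1 RPM. Windows named in the text are, for each comparison, among the 5 most abundant in the control and the 8 largest decreases and 7 largest increases in log2 ratio among windows with at least 50 RPM in the higher library. For the oocyte library they are among its 10 most abundant. Windows with under 50% uniquely matching reads are called uncertain.

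The 26-nt windows, defined after the data were seen, had a mean of at least 5 RPM of 26-nt reads over the CIP-PNK libraries, with at least 60% of the reads of 25 to 27 nt being 26 nt long.

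Intervals are exact at the 95% level: binomial for shares and for RPM values, and conditional binomial for ratios, with fractional counts rounded. They cover counting error only, since PCR copies are not independent molecules. Intervals of medians come from order statistics over windows and describe the windows of these libraries. A count that rounded to 0 was replaced by a floor of 3 counts per library, and the fold is then given as at least that value. A median of a window class was placed among the medians of 10000 random lists of the same size, matched in 20 bins on the mean RPM of the 2 libraries compared. Overlaps of lowered windows were set beside n1 × n2 / N and beside 100 simulations of unchanged strains against the shared wild-type library.

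The 3 window classes were defined after the data were seen, from 4 libraries that enter no comparison of a mutant with wild type by CIP-PNK. The 4602 windows with at least 10 RPM in the higher of the 2 Terminator libraries and in the higher of the WAGO-1 IP and its input were used, and IP to input ratios were taken after scaling to 22-nt-class reads. IP-enriched windows had a ratio of at least 2. IP-depleted windows had a ratio at or under 1 over 2, and were divided into those at least 2-fold lower and those at least 2-fold higher in glp-4 than in wild type, called germline and glp-4-high. An earlier definition on RPM is kept as an alternative.

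The calling step was tested on simulated counts with 200 windows changed by known folds in each of the 10 comparisons. It recovered from 96.5% of them in drh-3 to 98.5% in WAGO-1 IP and in glp-4, and called at most 0.143% of unchanged windows. All changes exceeded the 2-fold threshold, were made in windows with at least 25 RPM in the control, and carried counting error only. These values check the calling step and are no error rate between real libraries. Alternatives fixed before the data were examined were scaling to point loci, to 21-nt ends or to all reads, uniquely matching reads only, reads of any length, a floor of 10 RPM, a pseudocount of 10 RPM, a 4-fold threshold for overlaps and 26 nt in place of 25 to 27 nt. Scaling to 22-nt-class reads, windows moved by 500 nt, the smg-5 library as control other class definitions and 26-nt windows picked without mut-7 and rde-3 were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pyarrow 21.0.0 and matplotlib 3.10.9 was used.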

Results

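Small RNAs of Caenorhabditis elegans, a nematode, were compared between wild type and strains mutant in genes of the WAGO pathway, in which worm-specific Argonaute proteins bind 22-nt RNAs made by RNA-dependent RNA polymerases. The 14 groups held 1 distinct library each. By CIP-PNK, which clones RNAs with any number of 5′ phosphates, there were wild type with 2342699 reads, drh-3 with 4328545, ekl-1 with 3016406, rrf-1 ego-1 with 4481322, mut-7 with 3014416, rde-3 with 3011087, MAGO12 with 3326295, smg-5 with 3923558 and rde-4 with 3774356. A WAGO-1 immunoprecipitate (IP) held 3367275 reads and its input from young adults 3333131. By the Terminator protocol, which removes RNAs with a 5′ monophosphate, wild type held 4007024 reads and glp-4 adults, which lack a germline, 1494243. Oocytes from fem-1 animals, cloned after pyrophosphatase (TAP), held 5359617 reads. The rrf-1 ego-1, ekl-1 and rde-4 animals were labelled adults and the other mutants and wild type gravid adults.

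The makeup of the libraries differed by protocol and by strain. The 22-nt class, reads of 21 to 23 nt outside the other kinds, made up 50.4% of the reads outside the end block and mitochondrial DNA in wild type by CIP-PNK (95% interval 50.3 to 50.5). It fell to 9.31% in drh-3, 12.9% in ekl-1, 10.7% in rrf-1 ego-1, 19.9% in mut-7, 19.7% in rde-3 and 11.9% in MAGO12. It was 29.4% in smg-5 and 42.6% in rde-4. Point loci, sharp-ended sites that stand in for microRNAs, made up 24.3% in wild type by CIP-PNK and 0.570% by Terminator, and 32.1% in the WAGO-1 input against 2.64% in the IP. The 21-nt ends on chromosome IV, which stand in for Piwi-bound 21U-RNAs, took 8.11% in wild type by CIP-PNK, 0.214% by Terminator and 0.849% in the IP. Intron-spanning reads made up 2.50% in wild type and 0.337% in drh-3. Read length differed too: reads of 17 to 19 nt made up 8.04% in wild type, 9.74% in drh-3 and 7.77% in rde-4. They made up 22.2% in mut-7, 25.7% in rde-3, 30.2% in smg-5, 34.1% in rrf-1 ego-1, 34.7% in ekl-1 and 39.2% in MAGO12.

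**Figure D1:**
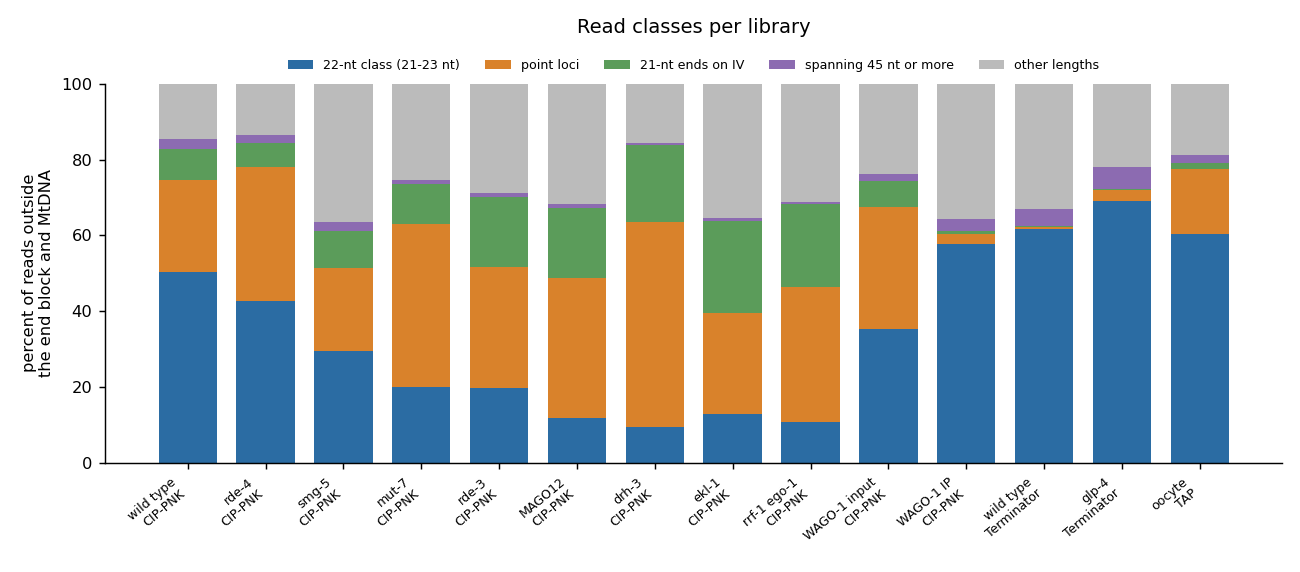
Stacked bars give the percent of reads outside the end block and mitochondrial DNA in each read kind, 1 bar per library. The 22-nt class falls from 50.4% in wild type by CIP-PNK to 9.31% in drh-3.

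Sharp 5′ ends with a 21-nt profile lay mostly on chromosome IV, the chromosome known to hold the 21U-RNA genes. Of all such ends 6494 lay there, and 1557 on the other chromosomes together. On chromosome IV 6277 of the ends (96.7%) lay from 4 to 7 Mb or above 13 Mb. The 88 point loci, which exclude 92 on chromosome IV of 20 or 21 nt that were moved to the 21-nt ends, were spread over all chromosomes, with 26 on X and 22 on II.

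**Figure D2:**
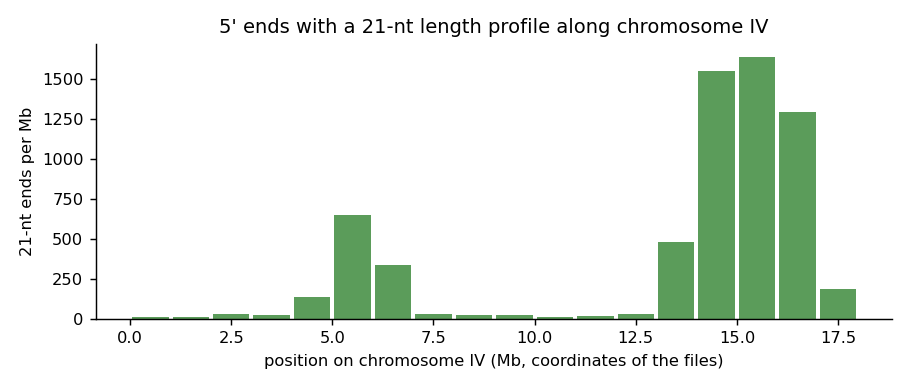
Bars give the number of 5′ ends with a 21-nt length profile in each Mb of chromosome IV, picked on the CIP-PNK libraries together. Of the 6494 ends, 1124 lie from 4 to 7 Mb and 5153 above 13 Mb.

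In drh-3, mutant in a Dicer-related helicase, 22-nt-class reads were lost over most of the windows with enough reads. Of 3295 windows with enough reads, 2795 were lower and 352 higher than in wild type. The count of higher windows depended on the setting, from 79 scaled to all reads to 1206 with reads of any length. The window with most reads in wild type, on the minus strand of X from 9072001 to 9073000, fell from 5291 to 56.2 RPM (94.2-fold, interval 79.9 to 112), but only 46.4% of its reads matched uniquely, so it is uncertain. The plus-strand window of I from 12095001 to 12096000 fell from 3957 to 37.3 RPM (106-fold), and the minus-strand window of IV from 6354001 to 6355000 from 2949 to 29.1 RPM (101-fold). No read was left of 486 RPM on the plus strand of V from 17425001 (at least 415-fold lower) or of 319 RPM on the minus strand of X from 5416001 (at least 272-fold lower). Increases were smaller: the largest was on the minus strand of IV from 2655001, to 52.5 RPM (14.7-fold, 7.32 to 39.3). The window on the minus strand of II from 15165001 rose from 5.30 to 62.8 RPM (11.9-fold), and that on the plus strand of V from 11782001 from 8.19 to 78.8 RPM (9.63-fold). Of the windows called higher, 40.6% held mainly reads with several matches, against 17.6% of those called lower. The median log2 ratio was -4.94, and scaling to point loci moved it by -1.16 and scaling to 22-nt-class reads by 2.44, with the sign kept.

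The ekl-1 strain, mutant in a Tudor-domain protein, and the rrf-1 ego-1 strain, mutant in a pair of RNA-dependent RNA polymerases, lost 22-nt-class reads in many of the same windows. In ekl-1 2759 of 3325 windows were lower and 442 higher, and in rrf-1 ego-1 2792 of 3130 were lower and 230 higher. The IV window from 6354001 was 58.6-fold lower in ekl-1 (46.1 to 75.7) and 55.2-fold lower in rrf-1 ego-1 (45.7 to 66.8). The I window from 12095001 fell less, 4.35-fold in ekl-1 and 12.9-fold in rrf-1 ego-1. The uncertain X window from 9072001 fell 6.49-fold in ekl-1 and 1.62-fold in rrf-1 ego-1, to 3262 RPM. On the plus strand of II from 2298001, 195 RPM in wild type left no read in ekl-1 (at least 86.7-fold lower). On the minus strand of II from 7300001, 176 RPM left none in rrf-1 ego-1 (at least 125-fold lower). The minus-strand window of III from 10506001 was higher in both, at 85.7 RPM in ekl-1 and 61.7 RPM in rrf-1 ego-1 against 2 reads (0.963 RPM) in wild type, ratios of 88.9 (24.1 to 743) and 64 (17.4 to 534). The commonest read length in this window was 20 nt in ekl-1 and 19 nt in rrf-1 ego-1, shorter than the 22-nt class. On the plus strand of V from 4310001 ekl-1 was 40.8-fold higher, at 338 RPM. Of the windows called higher, 59.5% in ekl-1 and 65.2% in rrf-1 ego-1 held mainly reads with several matches. Windows lower in both strains numbered 2745 of 3064 tested, against 2514 for independent lists and 0.04 for simulated unchanged strains. Only 2909 windows reached 25 RPM in wild type and could be lower, so the value for independent lists is too low. With reads of any length 2512 windows were higher in ekl-1 and 2469 in rrf-1 ego-1, and scaled to all reads 130 and 71. With the smg-5 library as control, a setting added after seeing the data, 1633 of 2208 windows were lower in ekl-1 and 1647 of 1998 in rrf-1 ego-1. The median log2 ratio was -4.30 in ekl-1 and -3.97 in rrf-1 ego-1, and scaling to 21-nt ends moved it by -1.58 and -1.43 and to 22-nt-class reads by 1.97 and 2.24, with the sign kept.

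In mut-7, mutant in a protein with an exonuclease domain, and rde-3, mutant in a nucleotidyltransferase-like protein, the loss was again broad, but more windows were higher than in drh-3. In mut-7 2577 of 3424 windows were lower and 466 higher, and in rde-3 2664 of 3732 were lower and 755 higher. The strains parted at the most abundant windows: the I window from 12095001 was 5.79-fold lower in mut-7 (5.45 to 6.15) and 139.8-fold lower in rde-3 (104 to 188), and the X window from 9072001, uncertain in rde-3, 2.42-fold and 154-fold lower. The IV window from 6354001 fell alike, 9.81-fold in mut-7 and 8.63-fold in rde-3. On the plus strand of V, 394 RPM from 17426001 and 392 RPM from 17315001 left no read in rde-3, at least 220.4-fold and 219-fold lower. On the plus strand of V from 10048001, 222 RPM left no read in mut-7 (at least 134-fold lower). The plus-strand window of I from 2410001 rose in both, from 10.2 to 419.6 RPM in mut-7 (41.2-fold) and to 474 RPM in rde-3 (46.5-fold). The minus-strand window of II from 15165001 was 53.2-fold higher in rde-3, at 282 RPM. Windows lower in both strains numbered 2510 of 3348, against 2050.5 for independent lists and 0.11 for simulated unchanged strains. Of these 3348 only the 2909 or fewer with 25 RPM in wild type could be lower, so the value for independent lists is too low. In rde-3 lower windows were 77.9% of those called, and 90.0% when scaled to 21-nt ends (2810 lower and 313 higher) or 92.4% when scaled to all reads (2474 and 204). The median log2 ratio was -3.31 in mut-7 and -3.95 in rde-3, and scaling to point loci moved it by -0.83 and -0.39, to 21-nt ends by -0.36 and -1.19, and to 22-nt-class reads by 1.34 and 1.35.

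In MAGO12, a strain carrying mutations in many WAGO-clade Argonaute genes, the loss was as deep as in drh-3. Of 3176 windows 2754 were lower and 233 higher, with a median log2 ratio of -5.01, which scaling to point loci moved by -0.61 and to 22-nt-class reads by 2.08. No read was left of 681 RPM on the plus strand of V from 1698001 (at least 439.9-fold lower), of 578 RPM on the minus strand of III from 835001 (at least 373.5-fold lower) or of 506 RPM on the plus strand of IV from 16837001 (at least 327-fold lower). The minus-strand window of X from 13397001 to 13398000 fell 183-fold, from 2024 RPM. The largest increase was on the minus strand of X from 11791001, to 454.0 RPM (11.4-fold, 9.06 to 14.4). This library had the largest share of reads of 17 to 19 nt, and with reads of any length 3130 windows were lower and 2811 higher.

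Across these 6 strains the same windows were lowered. Of 2909 windows with enough reads in wild type, 2419 (83.2%) were lower in drh-3, ekl-1, rrf-1 ego-1, mut-7, rde-3 and MAGO12, and 26 were lower in none. All share the wild-type library, and part of the excess of overlap over independent lists may come from it. For drh-3 and MAGO12 the windows lower in both numbered 2702, against 2573 for independent lists and 0.07 simulated, and the covariance of log2 ratios was 3.81 against 0.0234 simulated. For ekl-1 and MAGO12 the covariance was 2.79 against 0.0240, and for mut-7 and rde-3 6.31 against 0.0240. The simulations hold counting error only, while log2 ratios of single 21-nt ends also correlated between libraries, at 0.933 for mut-7 and rde-3 and 0.748 for ekl-1 and rrf-1 ego-1, so part of these overlaps may come from how the libraries were made. This correlation was also high for ekl-1 and smg-5 (0.743), MAGO12 and smg-5 (0.718) and ekl-1 and MAGO12 (0.643), and the wild-type control, with 8.04% of reads of 17 to 19 nt, is unlike these libraries in read length. The minus-strand window of X from 9192001, IP-enriched, was among the largest decreases in drh-3, ekl-1, rrf-1 ego-1, mut-7 and MAGO12, but its 843 RPM in wild type by CIP-PNK also stood against 28.6 RPM in smg-5, 6.84 RPM in rde-4, 18.0 RPM in the input and 192 RPM in wild type by Terminator. The WAGO-1 input set against wild type gives a measure of the differences between libraries of strains with an intact pathway. It also includes stage, since the input came from young adults and wild type from gravid adults. In it 1423 of 3367 windows were lower and 434 higher, and 981 and 684 when scaled to 22-nt-class reads. The shift was uneven, with median log2 ratios of -1.49 in IP-enriched and 0.43 in IP-depleted glp-4-high windows. The input helped define these classes, since a low input favours the IP-enriched and a high input the IP-depleted kind. Part of this unevenness is therefore built in, and it is no measure of differences between libraries.

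In smg-5, mutant in a gene of nonsense-mediated decay, windows fell less than in the strains above. Whether more of them fell than in the WAGO-1 input set against wild type, which also differs in stage, depended on the scale. Of 3035 windows 1278 were lower and 79 higher, with a median log2 ratio of -0.85. The share of lower windows among those called was 94.2%, and 69.4% scaled to 22-nt-class reads (426 lower and 188 higher), a scaling that moved the median by 0.78. Scaled to 21-nt ends 1929 were lower and 64 higher, with the median at -1.16. Lower windows in the input against wild type numbered 1423 on RPM, 981 scaled to 22-nt-class reads and 1253 scaled to 21-nt ends. Scaled to all reads there were 1647 lower in smg-5 and 1310 in the input, and scaled to point loci 996 and 1760. Some windows were nearly lost: the plus strand of IV from 4242001 to 4243000 held 188 RPM in wild type and no read in smg-5 (at least 180.3-fold lower), and the minus strand of III from 3153001 to 3154000 fell from 1196 to 17.1 RPM (70.1-fold). On the minus strand of III from 7669001 the fall was 91.8-fold, from 527 to 5.74 RPM. The minus-strand window of II from 2876001 was higher at 213 RPM against 2 reads in wild type (ratio 221, interval 61.0 to 1831), but this window was also higher in rde-4 and rde-3, at 104 and 86.4 RPM, and wild type by Terminator held 4.33 RPM. With reads of any length 505 windows were lower and 927 higher in smg-5.

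In rde-4, mutant in a double-stranded RNA-binding partner of Dicer, a limited set of windows was almost emptied while most of those with enough reads stayed within 2-fold of wild type. Of 3188 windows 589 were lower and 198 higher, with a median log2 ratio of -0.21. The uncertain X window from 9072001 fell from 5291 to 10.2 RPM (519-fold, 361 to 765), and its neighbour from 9071001, with unique reads, from 1352 to 6.15 RPM (219.7-fold, 139 to 371). The III window from 3153001 was 233-fold lower (141 to 417), and the minus strand of II from 13473001 fell from 616 to 0.854 RPM, with 2.5 reads left (ratio 0.00139, interval 0.00013 to 0.00401). The IV window from 6354001 was 1.21-fold lower and the minus-strand window of I from 13853001 to 13854000 1.04-fold lower. The minus strand of I from 4684001 rose 52.2-fold, from 3.13 to 163 RPM. A point locus lies in this window on the same strand, at 4684400, with 85.7 RPM in wild type and 477 RPM in rde-4. Only reads starting within 6 nt of its end were set apart, so the rise may hold other reads of that locus. Of the 272 windows at least 4-fold lower in rde-4, a set picked on this comparison, the reads made up 72.5% of the 22-nt class in glp-4 and 9.22% in wild type by Terminator, and 1.43% in the WAGO-1 IP against 12.5% in its input. Of the 272, 122 were IP-depleted glp-4-high and held 98.2% of these reads in glp-4, and the median log2 ratio in glp-4 was 0.67, with an interval from 0 to 1.38. Lower windows were 74.8% of those called, but 92.3% scaled to point loci (1182 lower and 98 higher), 49.1% scaled to 21-nt ends (380 and 394) and 59.6% scaled to 22-nt-class reads (449 and 305), and the median turned to 0.19 with 21-nt ends and to 0.04 with 22-nt-class reads.

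The WAGO-1 IP asks which 22-nt RNAs this Argonaute binds. Against its input 2005 of 3596 windows were higher and 192 lower, so that lower windows were 8.74% of those called. Scaled to 22-nt-class reads 360 were higher and 234 lower, and lower windows were 39.4%, since the 22-nt class rose as a whole from 35.3% of reads in the input to 57.7% in the IP. The largest increase was on the plus strand of III from 9717001, from 7.57 to 84.1 RPM (interval of the fold 7.12 to 18.2). The plus strand of V from 17700001 rose 7.36-fold to 220.1 RPM and the minus strand of X from 14375001 6.56-fold. The I window from 13853001 rose 2.39-fold, to 3041 RPM. Against these, the III window from 3153001 fell from 2279 RPM in the input to 134 RPM in the IP, and the minus strand of IV from 3579001 was 16.2-fold lower. The minus strand of V from 15426001 fell from 740.3 to 9.65 RPM (76.7-fold).

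In glp-4 adults, compared with wild type by Terminator, 22-nt RNAs from most windows with enough reads were lower and a small set was much higher. Of 4196 windows 3543 were lower and 318 higher, with a median log2 ratio of -2.40. RPM are shares of a library, so the lower and the higher windows are not separate results. The IP-depleted glp-4-high windows went from 45647 RPM in wild type to 526881.5 RPM in glp-4, while the whole 22-nt class took 61.7% and 69.05% of reads. A rise of these windows lowers the RPM of the others, and a loss of the others raises theirs. On the plus strand of I from 9710001 reads fell from 907 to 2.99 RPM (303-fold, 118 to 1113), and on the minus strand of II from 7122001 from 783 to 10.5 RPM (74.7-fold). The IV window from 6354001 was 6.53-fold lower and the I window from 13853001 3.98-fold lower. The III window from 3153001 was 4.08-fold higher, at 16330.1 RPM against 3998. The X window from 9072001 was 7.20-fold higher, at 27172 RPM. The plus strand of II from 3314001 rose from 33.1 to 2544 RPM (76.8-fold, 64.5 to 92.2) and the plus strand of IV from 4894001 from 51.1 to 3452 RPM (67.6-fold, 58.8 to 78.4). Scaling to point loci, which the Terminator enzyme depletes, moved the median by -2.34.

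Windows grouped by the IP and by glp-4 responded differently to the mutations. There were 404 IP-enriched, 371 IP-depleted germline and 207 IP-depleted glp-4-high windows. By construction they differ in the IP and the glp-4-high ones hold more reads in glp-4: these made up 76.3% of the 22-nt class in glp-4 and 7.40% in wild type by Terminator. Germline windows of the IP-depleted kind were rare on X, with 6 of 371 (1.62%, 0.596 to 3.49), against 18.1% of IP-enriched windows and 12.5% of all 4602. Of the autosomal ones, 38.4% lay in the central part of their chromosome, 1 of 3 equal parts, against 21.5% of IP-enriched, 6.51% of glp-4-high and 24.6% of all windows.

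**Figure D3:**
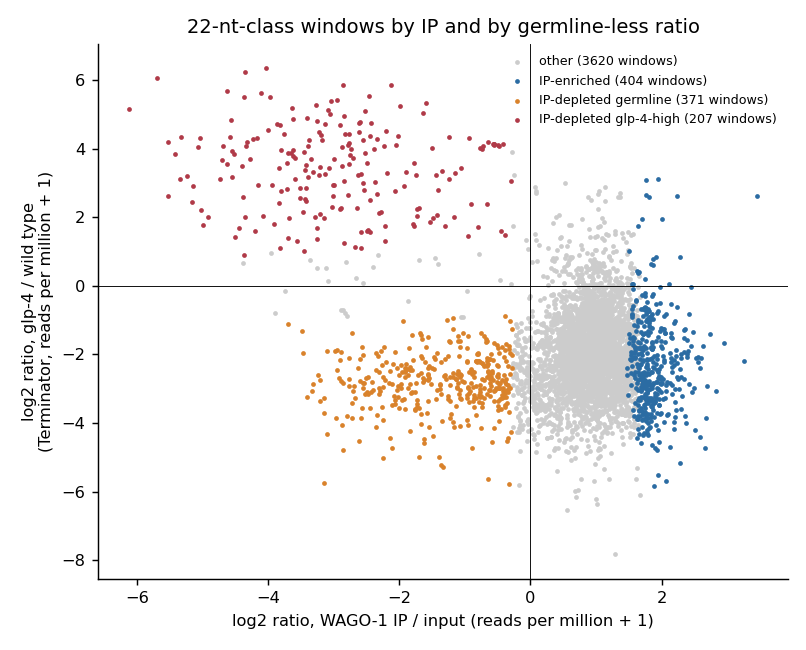
Each point is 1 of the 4602 windows, placed by the log2 ratio of IP to input and of glp-4 to wild type by Terminator, both on RPM with a pseudocount of 1. Colours give the 404 IP-enriched, 371 IP-depleted germline and 207 IP-depleted glp-4-high windows.

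IP-enriched windows were lowered in all 6 strains named above, with median log2 ratios of -4.33 in drh-3, -4.04 in ekl-1, -3.72 in rrf-1 ego-1, -3.33 in mut-7, -3.86 in rde-3 and -4.49 in MAGO12, and they stood at -0.54 in smg-5 and -0.02 in rde-4. IP-depleted germline windows were lowered in ekl-1 (-3.73) and rrf-1 ego-1 (-3.64) and less in drh-3 (-1.82). In ekl-1 and rrf-1 ego-1 a run of 7 point loci on II abundant in oocytes was also low, at 4364 and 1839 RPM against 24598 in wild type. The IP-depleted germline windows lay near wild type in mut-7 (-0.03, interval -0.23 to 0.18), rde-3 (0.02, -0.16 to 0.22) and MAGO12 (-0.36, -0.69 to -0.20), but scaled to point loci at -0.79, -0.36 and -0.93. This held for the class as a whole and not for its more abundant windows: in the 46 that remain with classes set at 25 RPM, a setting added after seeing the data, the medians were -1.10 in mut-7, -2.41 in rde-3 and -3.32 in MAGO12, against -4.50 in ekl-1 and -4.21 in rrf-1 ego-1. In mut-7, rde-3, MAGO12 and drh-3 the median of all 371 lay above the medians of all 10000 random lists matched on mean RPM. That mean includes the mutant library, so the lists are not matched on abundance in wild type. The placement cannot tell a trait of the class from its abundance in wild type. Relative to IP-enriched windows of the same library, a difference that scaling changes only through the pseudocount, the 371 windows were higher by 3.30 in mut-7, 3.87 in rde-3, 4.12 in MAGO12 and 2.50 in drh-3, and by 0.31 in ekl-1 and 0.08 in rrf-1 ego-1. IP-depleted glp-4-high windows had medians of -3.50 in rde-4, -1.82 in smg-5, -3.69 in rde-3, -4.21 in drh-3 and -2.31 in MAGO12. They stood at 0.08 (-0.33 to 0.38) in ekl-1, -0.64 in rrf-1 ego-1 and -0.45 in mut-7, but scaled to point loci at -0.06, -1.16 and -1.23. In ekl-1 they made up 38.6% of the 22-nt class and in rrf-1 ego-1 27.6%, against 7.98% in wild type and 0.945% in rde-4. Summed, they held 49673 RPM in ekl-1, 29366 RPM in rrf-1 ego-1 and 40250 RPM in wild type, so the shares rose mainly as the rest of the class fell. With a pseudocount of 10 RPM the differences between the classes shrank, to 1.57 in mut-7, 1.66 in rde-3 and 1.58 in MAGO12 for germline windows.

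**Figure D4:**
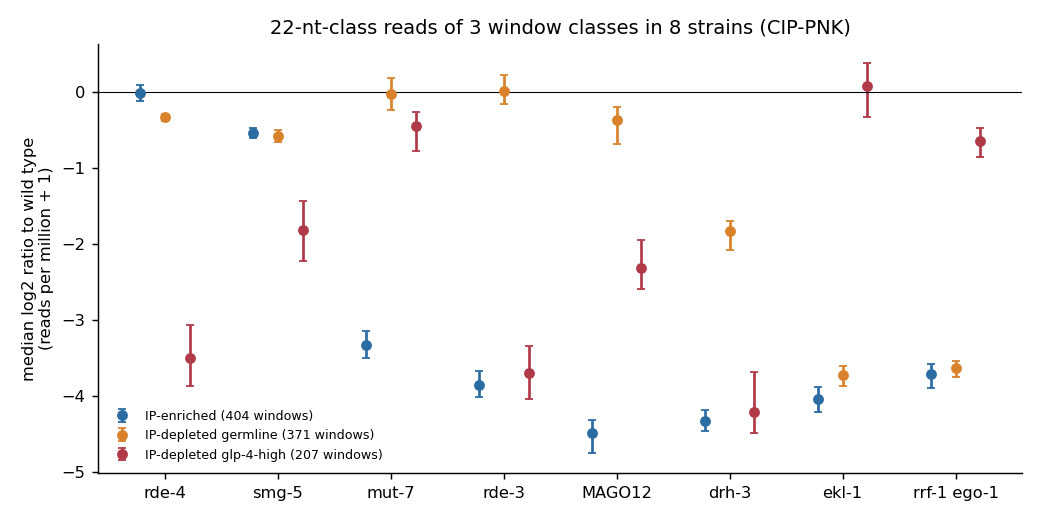
Points give the median log2 ratio of each window class to wild type by CIP-PNK (RPM with a pseudocount of 1), and bars the 95% interval of the median over windows. IP-depleted germline windows lie near 0 in mut-7 (-0.03) and rde-3 (0.02), and at -3.73 in ekl-1.

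The oocyte library has no control of its protocol, and its windows are given as levels. Its most abundant window, on the minus strand of II from 13478001 to 13479000, held 7245 RPM, against 12450.0 RPM in glp-4 and 846 RPM in wild type by Terminator. Neighbouring windows on the minus strand of X from 17253001 and 17254001 held 5079 and 4560.1 RPM in oocytes, 4.51 and 3.11 RPM in the WAGO-1 IP, and 14.4 and 3.93 RPM in rde-4. The minus strand of IV from 14937001 held 4184 RPM in oocytes, 183 RPM in wild type by CIP-PNK and 6.44 RPM in rde-4. The X window from 13397001 went the other way, with 2729.7 RPM in oocytes, 1970.1 RPM in the IP and 1709 RPM in rde-4.

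Reads of 26 nt mark a class of primary small RNAs of the worm (26G-RNAs), and 25 windows held them as the main length between 25 and 27 nt. Summed over these windows they reached 576 RPM in wild type (544 to 610) and 2639 RPM in mut-7 (2565 to 2715), a 4.58-fold rise (4.30 to 4.88). The windows were picked on libraries that include mut-7 and rde-3. In the 7 that are picked without these, a choice added after seeing the data, the rise was 3.82-fold (3.47 to 4.23), with 6 at least 2-fold higher, and 2.15-fold when scaled to point loci. The rise in mut-7 was not particular to these windows, since reads of 25 to 27 nt outside them went from 6206 RPM in wild type to 31149 RPM. In the 25 windows the 26-nt reads fell to 52.2 RPM in rde-4 (fold interval 9.31 to 13.1). In ekl-1 they were 7.80-fold, in rrf-1 ego-1 5.23-fold, in MAGO12 4.47-fold, in drh-3 4.25-fold and in rde-3 1.98-fold lower, and in smg-5 they stood at 632 RPM. The window on the plus strand of II from 2136001 held 85.7 of the 110 RPM in rrf-1 ego-1 and 38.3 of the 52.2 RPM in rde-4. It also held 256 RPM in the WAGO-1 IP against 73.6 RPM in its input. The falls over the other windows were therefore deeper in these 2 strains, and the order of the strains rests partly on this window. Of the 25 windows 13 were IP-depleted glp-4-high and 5 IP-depleted germline windows. The plus-strand window of V from 19290001 rose from 28.9 RPM of 26-nt reads in wild type to 335 RPM in mut-7 and held 1.37 RPM in rde-4. Over the whole genome reads of 25 to 27 nt made up 0.696% of reads in wild type and 3.48% in mut-7, and also 2.43% in drh-3, 2.49% in rde-3 and 2.62% in ekl-1, where the 26-nt windows fell.

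**Figure D5:**
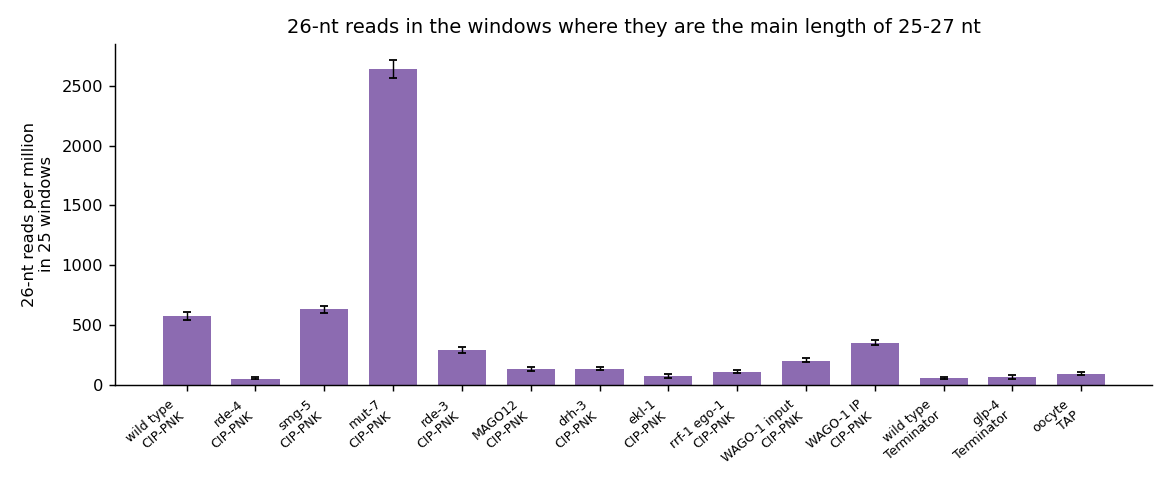
Bars give RPM of 26-nt reads summed over the 25 windows in each library, with exact binomial 95% intervals. The mut-7 library reaches 2639 RPM, above the 576 RPM of wild type, and rde-4 holds 52.2 RPM.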

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

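Each result here is a signal in reads that the comparisons leave out, at 2 or more times the share in the control library of the same protocol. The rde-4 library lay just under this for the end block, at 22.3%. The control share was 11.3% for the end block of chromosome I and 0.126% for mitochondrial reads in wild type CIP-PNK, and 1.98% and 0.0708% in wild type Terminator. No explanation was tested for these shares, and each rests on 1 library.

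The end block held 40.5% of all reads in drh-3, 55.6% in ekl-1, 52.3% in rrf-1 ego-1, 39.5% in mut-7, 44% in rde-3, 41.3% in MAGO12 and 26.4% in smg-5. Mitochondrial reads made up 0.311% in drh-3, 0.306% in ekl-1, 0.313% in rrf-1 ego-1, 0.318% in mut-7, 0.267% in rde-3, 0.402% in MAGO12 and 0.370% in smg-5. The WAGO-1 input, also by CIP-PNK but from young adults, held 0.693% mitochondrial reads, more than any of these strains, and 16.1% in the end block, less than any of them. A raised mitochondrial share is therefore not particular to the mutants. In glp-4, the strain without a germline, the end block held 8.77% and mitochondrial reads 1.80% of all reads.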

How the results depend on the processing

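Each group holds 1 library, so no replicate could be left out. No paired analysis was possible because each group holds 1 distinct library. The position of reads along transcripts under other settings and the fixed gene lists were not run. The wording of lower and higher counts below is as in the results, and a value is given where it lay outside 1.5 times the main count or, for shares, for ratios of 26-nt reads and for differences between class medians, outside the main interval. The class medians themselves are given as counts, apart from those named. The cause of these shifts was not tested, except where the setting itself sets the number of windows, as the floor of 10 RPM does. The alternatives added after seeing the data are named as such.

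The main counts of lower windows were 2795 in drh-3, 2759 in ekl-1, 2792 in rrf-1 ego-1, 2577 in mut-7, 2664 in rde-3, 2754 in MAGO12, 1278 in smg-5, 589 in rde-4, 192 in the WAGO-1 IP and 3543 in glp-4. The main counts of higher windows were, in this order, 352, 442, 230, 466, 755, 233, 79, 198, 2005 and 318. With windows moved by 500 nt, added after seeing the data, all 20 counts lay within 1.5 times the main ones.

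Scaled to point-locus reads, lower windows numbered 1182 in rde-4 and 36 in the WAGO-1 IP, and higher windows 156 in drh-3, 266 in mut-7, 146 in MAGO12, 98 in rde-4, 3458 in the WAGO-1 IP and 164 in glp-4. Scaled to 21-nt-end reads, lower windows numbered 1929 in smg-5, 380 in rde-4 and 51 in the WAGO-1 IP, and higher windows 130 in drh-3, 313 in rde-3, 64 in MAGO12, 394 in rde-4 and 3433 in the WAGO-1 IP. Scaled to all reads, higher windows numbered 79 in drh-3, 130 in ekl-1, 71 in rrf-1 ego-1, 186 in mut-7, 204 in rde-3, 43 in MAGO12, 39 in smg-5 and 112 in rde-4. Scaled to 22-nt-class reads, an added setting, lower windows numbered 426 in smg-5, and higher windows 355 in rrf-1 ego-1, 704 in mut-7, 428 in MAGO12, 188 in smg-5, 305 in rde-4 and 360 in the WAGO-1 IP. With uniquely matching reads only, higher windows numbered 208 in drh-3, 176 in ekl-1, 77 in rrf-1 ego-1, 290 in mut-7 and 141 in MAGO12. With reads of any length, lower windows numbered 505 in smg-5, 925 in the WAGO-1 IP and 6240 in glp-4. Higher windows then numbered 1206 in drh-3, 2512 in ekl-1, 2469 in rrf-1 ego-1, 1579 in mut-7, 2478 in rde-3, 2811 in MAGO12, 927 in smg-5, 364 in rde-4 and 3300 in the WAGO-1 IP. With a floor of 10 RPM, lower windows numbered 6257 in drh-3, 6574 in ekl-1, 6683 in rrf-1 ego-1, 5411 in mut-7, 5466 in rde-3, 5813 in MAGO12, 3064 in smg-5, 1670 in rde-4, 678 in the WAGO-1 IP and 9241 in glp-4. Higher windows were then 710, 982, 779, 1394, 2238, 908, 324, 512, 3720 and 514, in the same order. With the smg-5 library in place of wild type, also added, lower windows numbered 1633 in ekl-1, 1647 in rrf-1 ego-1 and 1587 in MAGO12.

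For the window classes, the values are log2 differences of a class median from the median of IP-enriched windows in the same library. For IP-depleted germline windows scaling to point loci gave 1.75 in drh-3, 2.98 in mut-7, 3.57 in rde-3 and 3.60 in MAGO12, a shift that comes from the pseudocount alone, which a scaling changes relative to the counts. A pseudocount of 10 RPM gave 0.70 in drh-3, 0.14 in ekl-1, 1.57 in mut-7, 1.66 in rde-3, 1.58 in MAGO12 and -0.22 in rde-4. Classes set at 25 RPM, an added setting with 46 such windows, gave 1.00 in drh-3, 2.52 in mut-7, 1.84 in rde-3, 2.2 in MAGO12, -0.47 in smg-5 and -0.59 in rde-4. The medians of the 46 windows themselves fell to -1.10 in mut-7, -2.41 in rde-3 and -3.32 in MAGO12, so that they no longer lay near wild type. Classes set on RPM, also added, gave 3.15 in drh-3, 0.47 in ekl-1, 3.97 in mut-7, 4.68 in rde-3, 4.84 in MAGO12, 0.27 in smg-5 and -0.23 in rde-4. Uniquely matching reads gave 3.56 in mut-7. For IP-depleted glp-4-high windows scaling to point loci gave -0.19 in drh-3, 2.82 in rrf-1 ego-1, 2.54 in mut-7 and 1.80 in MAGO12. A pseudocount of 10 RPM gave -0.39 in drh-3, 1.78 in ekl-1, 1.20 in rrf-1 ego-1, 1.25 in mut-7, -0.43 in rde-3, 0.39 in MAGO12, -0.80 in smg-5 and -1.93 in rde-4. Classes set at 25 RPM gave 4.80 in ekl-1, 3.61 in rrf-1 ego-1, 3.07 in MAGO12 and -4.20 in rde-4. With the smg-5 library in place of wild type the differences were 5.38 in ekl-1, 4.66 in rrf-1 ego-1 and 3.91 in MAGO12. The median itself of the glp-4-high windows in rrf-1 ego-1 changed sign there, from -0.64 to 1.50.

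With uniquely matching reads only, the 22-nt class made up 48.3% of reads outside the end block and mitochondrial DNA in wild type, 8.05% in drh-3, 10.9% in ekl-1, 8.44% in rrf-1 ego-1, 18.8% in mut-7, 18.9% in rde-3, 11.3% in MAGO12, 28.5% in smg-5, 40.5% in rde-4, 57.4% in the WAGO-1 IP, 32.7% in its input, 62.1% in wild type Terminator, 70.8% in glp-4 and 61.1% in oocytes. Reads of exactly 26 nt made up 0.323%, 0.904%, 0.888%, 0.370%, 1.44%, 0.817%, 0.228%, 0.442%, 0.333%, 0.550%, 0.488%, 0.136%, 0.930% and 0.0907%, in the same order, as part of the 25- to 27-nt reads. With 26-nt windows picked without mut-7 and rde-3, an added setting that left 7 windows, the ratio of their 26-nt reads went from 4.58 to 3.82 in mut-7 to wild type, from 0.504 to 0.616 in rde-3 to wild type and from 9.08 to 6.21 in mut-7 to rde-3. Scaled to 21-nt ends, also added, the median log2 ratio of the point loci in rde-3 went from 0.99 to -0.20, while in mut-7 it stayed within its interval. Among the overlaps, the class medians and the comparison of the input with wild type, 86 values under these settings lay within their bounds and 86 moved outside them, 6 of these with a change of sign, besides the rrf-1 ego-1 median of -0.64 that went to 1.50. The 6 are medians at most 0.36 from 0: germline windows in rde-3 went from 0.02 to -0.36 scaled to point loci and -2.41 with classes set at 25 RPM, in mut-7 from -0.03 to 0.46 and in MAGO12 from -0.36 to 0.13 with classes set on RPM, and in MAGO12 to 0.06 with the smg-5 library as control, while IP-enriched windows in rde-4 went from -0.02 to 0.11 at 25 RPM. Depth limits the windows of few reads: 1 read is 0.482 RPM in wild type and 0.748 RPM in glp-4.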

Other observations

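All tests in this part but 2 were chosen only after the result was seen: the scaling test of the 26-nt reads and the test of end preferences in mut-7 and rde-3 were set down before theirs. The tests of scaling and of fragments for the IP-depleted germline windows and that of a loss of microRNAs were first written for several strains together and were split by strain once their values were seen. What the tests of a branch not bound by WAGO-1 and of a loss of microRNAs would need was made stricter after their values were seen. Each pattern was found in single libraries, and what is said of its origin is a hypothesis.

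A run of 7 point loci lay on the plus strand of chromosome II between 11537584 and 11538284. Together they held 24598 RPM in wild type by CIP-PNK, 106122 RPM in oocytes, 2699 RPM in wild type by Terminator and 135.5 RPM in glp-4. They were low in rrf-1 ego-1 (1839 RPM) and ekl-1 (4364 RPM), whose animals were labelled adults and not gravid. They were above wild type in rde-4 (42123 RPM), labelled alike, and in drh-3 (69628 RPM) and mut-7 (81079 RPM), where point loci as a whole also rose. Of point-locus reads the run made up 10.1% in wild type, 11.9% in rde-4, 12.9% in drh-3 and 18.8% in mut-7. The share was 1.64% in ekl-1 and 0.516% in rrf-1 ego-1. The 7 loci may be a microRNA cluster of oocytes and embryos, of which the worm has a known one on this chromosome: their median log2 ratio of glp-4 to wild type lay -6.34 from that of the other 81 loci, as such a cluster would give. Egg content of the animals therefore stays open as a difference between the mutants and wild type.

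IP-depleted germline windows were near wild type in MAGO12, mut-7 and rde-3, and lowered in ekl-1, rrf-1 ego-1 and, less, drh-3, but this rests on the scale and on weaker windows: scaled to point loci the medians were -0.93 in MAGO12 and -0.79 in mut-7, and with classes set at 25 RPM -3.32 in MAGO12, -2.41 in rde-3 and -1.10 in mut-7. Scaling of the libraries is argued against for ekl-1 and rrf-1 ego-1, since the difference from IP-enriched windows within a library set them apart from the other strains by 2.99 log2 units, and by 1.43 with a pseudocount of 10 RPM and 1.66 at 25 RPM. For drh-3 the gap was 0.80, with 0.87 and 0.84 under these settings and 1.23 scaled to point loci, and scaling stays open. Less oocyte or embryo content stays open for ekl-1 and rrf-1 ego-1, where the run on chromosome II had medians at or under -2.38. It is argued against for drh-3, where the run stood at 1.54. All 88 point loci had a median of 1.20 there, so the run was not lower relative to them either. Fragments of abundant transcripts as the main reads of most windows are argued against in mut-7 and rde-3, where 22 nt was the commonest length in 65.5% and 58.8% of them. In wild type this share was 85.7%, so fragments stay open for the remaining windows and as a part of the class medians. In MAGO12 the share was 15.4%, near the 23.2% of the smg-5 library, so that there fragments cannot be told apart from a library of short reads. A branch of 22-nt RNAs that WAGO-1 does not bind stays open, since IP-depleted windows of 5 to 10 RPM lay 2.67 log2 units above IP-enriched ones in MAGO12 but fragments left out of the IP would give such a gap too.

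The 26-nt reads of 25 windows were 9.08-fold more abundant in mut-7 than in rde-3, and 6.21-fold in the 7 windows picked without these libraries. Oocyte or embryo content is argued against, since the run of point loci on chromosome II differed 1.18-fold, and so is a preference for longer reads, since 25- to 27-nt reads outside the windows differed 1.27-fold. Scaling is argued against too, as the ratio was at least 6.71 with either point loci or 21-nt ends as the scale, and at least 4.59 in the 7 windows. A difference between the strains in the making or stability of 26-nt RNAs may remain, with 1 library each. It concerns mut-7 against rde-3, since against wild type reads of 25 to 27 nt rose outside the windows too, from 6206 to 31149 RPM in mut-7.

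At 8 point loci reads were at least 4-fold lower in both mut-7 and rde-3, the largest fall being at 5′ position 7841674 on the plus strand of IV, from 1112 RPM in wild type to 12.7 and 4.17 RPM. A class-wide loss of microRNAs is argued against in mut-7, where the median log2 ratio of all 88 loci was 1.47, and 1.1 scaled to 21-nt ends, but stays open in rde-3, where it was 0.99 and, scaled to 21-nt ends, -0.20. A shared preference of these libraries for certain RNA ends could account for it: log2 ratios of single 21-nt ends, across ends that are not independent replicates, correlated at 0.933 between mut-7 and rde-3, against 0.748 in the next pair. A change of the same RNAs by both mutations was not tested.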
